A study of Mus musculus with 6 samples.

How the data were processed

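Polyadenylated RNA was sequenced from naive CD8 T cells, sorted from lymph nodes, in 3 WT and 3 CD103KO samples of the mouse. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with a stranded mRNA ligation kit. Per the submitters' processing notes, bcl2fastq 2.20, cutadapt 1.18, STAR 2.7.0f and RSEM were used with the builds GRCm38 and mm10. The RSEM version, the annotation release, the strand setting of the counting and the treatment of multiply aligned reads are not given in the sources used here. The authors deposited 1 table of expected counts per gene and library, estimates that need not be whole and are not normalized. Of its values, 6.48% were not whole, and all were rounded to whole numbers before testing. All 55450 gene identifiers, with their versions, matched GENCODE M21 on GRCm38, from which the coordinates come.

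Total counts were 68292475 to 94347034 per library, so that 1 count equals 0.0105 to 0.0147 CPM. Intervals and floors (3 counts) made from counts cover counting error only. Within each group, pairs of libraries differed by more than sampling noise (chi-square over its degrees of freedom 12.6 to 26.3), so none was treated as a library deposited a second time.

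The comparison was CD103KO against WT with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10), TMM normalization, the quasi-likelihood F test on group alone, and Benjamini-Hochberg adjustment at 0.05 over 13470 genes. CPM use TMM-scaled library sizes, and the standard error of a log2 fold change is its size divided by the square root of F. On simulated counts for the same 13470 genes, with 50 genes changed at each size, the test recovered 26% of genes changed 1.25-fold, 66% at 1.5-fold, 86% at 2-fold and 94% at 4-fold, and 10 of 146 calls were unchanged genes. Gene lists, 25 in all, were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists, with Itgae left out of each. Calls near Itgae were tested with a two-sided Fisher's exact test in a window of 5 Mb on either side, and shares of counts with exact two-sided permutation tests, for which 0.1 is the smallest p possible.

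The design, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took Itgae; the 10 rising and 10 falling called genes of smallest p with a mean of at least 1 CPM and no overlap between groups, passing over predicted genes and pseudogenes; for each list up to 3 called members, or the 2 of smallest p; Itgb7, Ly6c1, Ly6c2, Cxcr3, Cd8a and Cd8b1; and called genes within 5 Mb of Itgae. Outside the rule, and chosen after their values were seen, are Gm18860, Gm6685, Gm16425, Gm1821, Gm8797, 2610507I01Rik, 2310058D17Rik, Haspin, Cnot8, Cyb5d1, Larp1, Ubb, Ighm, Ighd, Cd79b, Cd74, Pou2af1, Cd4, Xist and Ddx3y. The values of 1 called gene are not reported here, though the counts include it. Sequence similarity was measured with megablast (BLAST+ 2.17.0) of GENCODE M21 transcripts of tested genes beyond 20 Mb of Itgae against those of genes within 20 Mb, at 90% identity over 300 bases.

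Alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom without and with sample quality weights, unrounded counts, an adjusted p of 0.01, a test against a fold of 1.2, the replicate number as a block, gene classes left out, each library left out, other windows (1, 10 and 20 Mb), an estimated correlation and fry for the lists. After seeing the data, a term for libraries with Xist reads (above 1 CPM) and a fit of only the libraries without them were added, as were an estimated correlation together with that term, list medians with each library left out and sums of called genes with their copies. SciPy 1.17.1 and matplotlib 3.10.9 were used for the sequence similarity test and the plots.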

Results

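RNA-seq was compared between naive CD8 T cells of 3 WT (C57BL/6) and 3 CD103KO samples from mouse lymph nodes. CD103 is the integrin alpha E chain encoded by Itgae, which pairs with integrin beta 7 and binds E-cadherin. The cells had been sorted as negative for Ly6C and CXCR3, surface markers of CD8 T cells with memory-like features. The comparison asks how the transcriptome of these resting cells differs when CD103 is missing. Total expected counts were 74438908, 94347034 and 80755359 in WT replicates 1, 2 and 3, and 73257508, 68292475 and 76044311 in CD103KO replicates 1, 2 and 3. Of 55450 genes in the table, 13470 had enough counts to be tested. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples. Within CD103KO that spread may be technical. Within WT it is not only technical. WT replicates 1 and 2 had 5012 and 7628 Xist counts and 0 of the Y-linked Ddx3y, against 1 and 4466 in WT replicate 3.

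Itgae (ENSMUSG00000005947.11, chromosome 11, 73090583 to 73147446, GRCm38, plus strand) averaged 482 ± 19.3 CPM (counts scaled to library size, SD, n = 3) in WT and 65.6 ± 3.90 CPM (SD, n = 3) in CD103KO. Its level was lower in every CD103KO library than in any WT library, with a log2 fold change of -2.88 (SE 0.06, adjusted p = 4.058e-08, edgeR quasi-likelihood test). CD103KO libraries thus kept 13.6% of the WT mean, from 4985, 4625 and 4622 counts against 36752, 47432 and 36561 in WT. Which exons those counts came from was not analysed here. Haspin, a mitotic kinase gene on the opposite strand within the span of Itgae, had a log2 fold change of -1.19 that did not pass (adjusted p = 0.0992, edgeR; 0.00803 with DESeq2), and its counts may share reads with Itgae. Itgb7, the partner chain, was at 870 ± 43.7 CPM in WT and 809 ± 17.6 CPM in CD103KO, with a log2 fold change of -0.11 that did not pass (adjusted p = 0.551, edgeR).

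**Figure D1:**
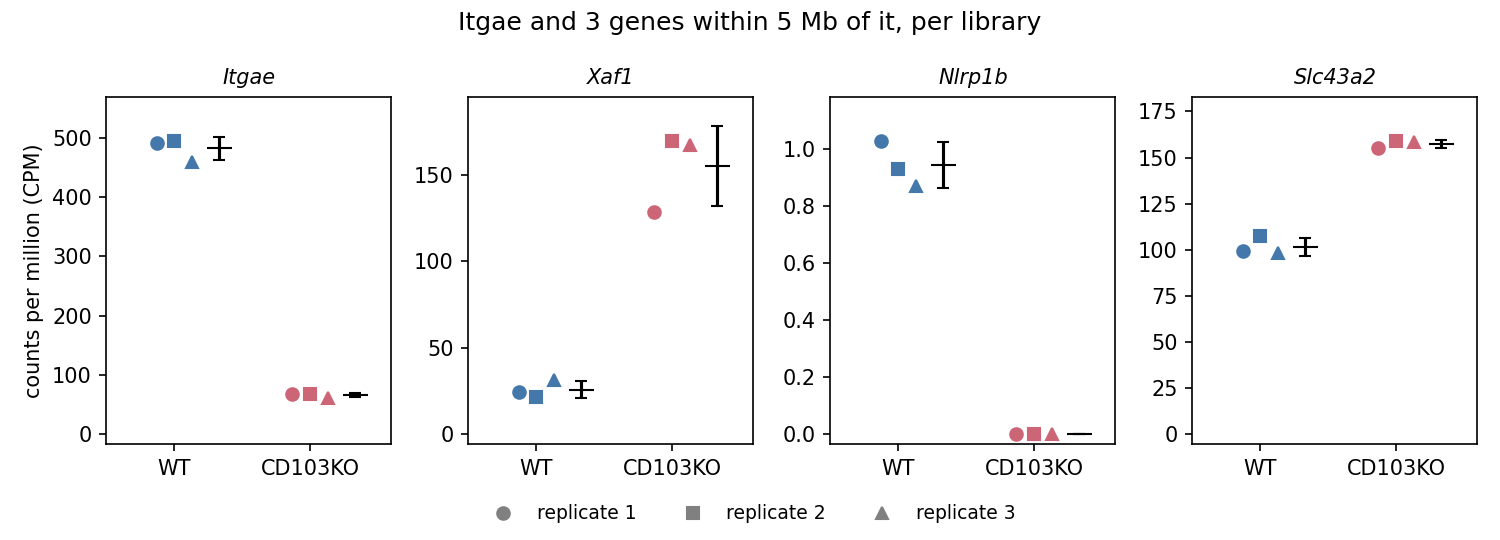
Levels in CPM (vertical axes, a separate scale per panel) of Itgae, Xaf1, Nlrp1b and Slc43a2 in each of the 3 WT (blue) and 3 CD103KO (red) libraries; black marks give the mean and SD. The groups do not overlap in any panel, and Nlrp1b had 0 counts in all 3 CD103KO libraries.

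Of the genes called with edgeR, 20 of 30 lay on the chromosome of Itgae. Xaf1, an interferon-inducible gene, rose from 25.6 ± 5.02 to 155 ± 23.3 CPM (n = 3 per group), 0.777 Mb from Itgae. Slc43a2, an amino acid transporter, rose from 102 ± 5.03 to 158 ± 2.22 CPM, and Nlrp1b, an inflammasome sensor, fell from 0.942 ± 0.0809 CPM to 0 counts. In all, 30 genes passed at an adjusted p of 0.05 (edgeR quasi-likelihood test), 19 higher and 11 lower in CD103KO, Itgae included. All 30 had groups that did not overlap, a property of 14.2% of tested genes where chance gives 10%. At an unadjusted p under 0.05 there were 1176 genes, and DESeq2 called 137, the 30 among them, of which 102 lay beyond 20 Mb of Itgae or on other chromosomes.

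Within 5 Mb of Itgae, 9 of 161 tested genes were called, against 20 of 13308 elsewhere (odds ratio 39.3, 95% interval 15.5 to 92.0, p = 3.2484e-11, two-sided Fisher's exact test, Itgae left out). Without WT replicate 1, 2 or 3 the window held 5, 5 and 6 calls, with odds ratios of 24.5, 25.1 and 11.2. Without CD103KO replicate 1, 2 or 3 it held 8, 4 and 5, with odds ratios of 13.8, 24.005 and 24.9. DESeq2 called 17 genes there (odds ratio 13.1), and 4 were called with a term for Xist reads (33.8). Called genes in this window that rose, beside Xaf1 and Slc43a2 (log2 fold changes of 2.60 and 0.63), were Tlcd2 (3.48), Eno3, a glycolytic enolase (0.55), Inpp5k, an inositol phosphatase (0.36), and Mink1, a kinase (0.30). Gosr1, a Golgi SNARE protein gene (-0.34), and 6330403K07Rik (-2.41) fell with Nlrp1b. For Nlrp1b, 235 counts in the WT group against 0 in the CD103KO group correspond to a level at least 68-fold lower, taking 3 counts over the group as the floor. At 20 Mb the window held 18 calls among 430 tested genes, 9 higher and 9 lower, against 11 among 13039 (odds ratio 51.7, p = 2.0943e-20, two-sided Fisher's exact test). Farther from Itgae on that chromosome, Trim16 (549 counts against 3, a ratio of 211 with a counting interval of 71.8 to 1025), Fbxw10 (2.44) and Zfp286 (1.12) rose. Galnt10, a glycosyltransferase (-0.56), Mapk7, a MAP kinase (-0.58), the histone gene Hist3h2ba (-1.80) and Zfp39 (-0.80) fell, as did the transcripts 2310058D17Rik (-2.46) and 2610507I01Rik (692 counts against 4, a ratio of 150.2 with a counting interval of 58.4 to 553). The annotations of Trim16 and Fbxw10 overlap on the same strand, so their counts may share reads. Apart from Gm6685, calls on the chromosome ran from Galnt10, starting at 57645442, to Gosr1, ending at 76763579. They did not fill that span, with 0 of 55 tested genes called from 65 to 70 Mb. Of those 55, 12.7% had an unadjusted p under 0.01 (edgeR), against 1.99% of genes on other chromosomes. Beside the span, from 50 to 55 Mb and from 80 to 85 Mb, the share was 0%. Farther out and with 0 calls, it was 11.1% of 27 genes from 30 to 35 Mb and 21.4% of 14 from 40 to 45 Mb. Such a share in 1 stretch therefore does not mark the span.

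**Figure D2:**
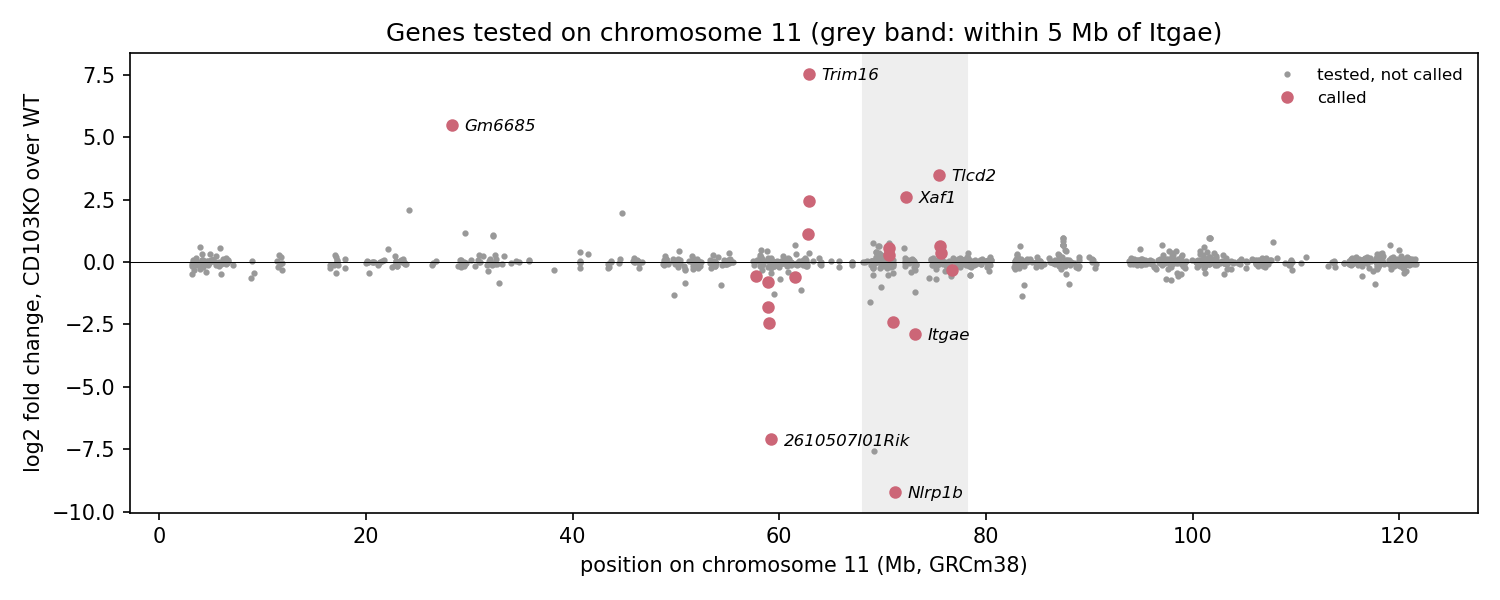
Log2 fold change of CD103KO over WT (vertical axis) against position in Mb on GRCm38 (horizontal axis) for each tested gene of chromosome 11, with called genes in red and others in grey, and a grey band for 5 Mb on either side of Itgae. The called genes span 19.12 Mb except Gm6685, and go in both directions, with 0 of 55 tested genes called from 65 to 70 Mb.

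The number of called genes depended on single libraries: it was 52 without WT replicate 3, 59 without CD103KO replicate 1 and 19 without CD103KO replicate 2, with 35, 40 and 7 of them outside the 20 Mb window. With no filter on low counts 83 of 112 were outside it. WT replicates 1 and 2 had 66.9 and 79.7 CPM of Xist and 0 counts of the Y-linked Ddx3y. WT replicate 3 and the CD103KO libraries had at most 2 Xist counts and 47.8 to 56.2 CPM of Ddx3y. Leaving out WT replicate 3 sets WT libraries with Xist reads against CD103KO libraries without them, so its 52 calls may include genes that differ with Xist state. A term for Xist reads therefore leaves a group effect of the CD103KO libraries against WT replicate 3 alone. With a term for Xist reads, chosen after seeing the data, 15 genes were called, 12 of them shared with the 30. The 12 were Itgae, Xaf1, Slc43a2, Tlcd2, Nlrp1b, Trim16, Fbxw10, Galnt10, 2610507I01Rik, Gm18860, Gm1821 and Gm6685. On chromosome 11 the calls of Zfp286, Inpp5k, Mink1, Mapk7, Gosr1, Hist3h2ba, Zfp39, Eno3, 6330403K07Rik and 2310058D17Rik were lost with that term. For the 18 lost calls in all, log2 fold changes with the term were 0.799 to 1.16 times those without it and standard errors 1.146 to 1.637 times. Zfp286, for example, went from 1.12 (SE 0.09) to 1.03 (SE 0.14, adjusted p = 0.0693, edgeR).

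Outside the 20 Mb window, 11 genes were called, 10 of them higher. Of these, 6 resemble a gene inside the window in sequence, at 90% identity or more over at least 300 bases, and their counts are uncertain for that reason. Gm18860 on chromosome 8 rose from 0.0685 ± 0.0392 to 4.23 ± 0.106 CPM and is 97.8% identical over 760 bases to Cnot8. Gm6685 (log2 fold change 5.49, 99.3% identical to Cyb5d1), Gm16425 (3.14, 93.1% identical to Larp1), Gm1821 (1.71) and Gm8797 (1.74) also rose, the last pair being 98.5% and 98.2% identical to the ubiquitin gene Ubb. None of Cnot8, Cyb5d1, Larp1 and Ubb passed with edgeR, with log2 fold changes of 0.21, 0.01, 0.04 and -0.14, but DESeq2 called Cnot8 (adjusted p = 0.0259). Gm18860 and Cnot8 summed to 70.8 ± 2.64 CPM in WT and 86.1 ± 3.31 CPM in CD103KO, and Gm6685 and Cyb5d1 to 9.82 ± 0.561 and 11.2 ± 0.223 CPM. The gain of Gm18860 alone, 4.16 CPM, was below both SDs of its sum, 5.95 CPM, so that sum cannot tell whether reads moved between the genes. The same held for every such pair except Gm6685 and Cyb5d1. Other calls were Scd1, a fatty acid desaturase (2.60), Slc15a2, a peptide transporter (0.92), and 3 B cell genes. The calls of Scd1, Slc15a2, Gm8797, Gm16425 and the 3 B cell genes were lost with the Xist term, with Scd1 at 2.75 (SE 0.38, against 0.23 without the term) and Fcer2a at 2.48 (SE 0.44, against 0.27).

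Genes that mark B cells were higher in CD103KO. Fcer2a, the low-affinity IgE receptor, rose from 0.141 ± 0.0138 to 0.849 ± 0.0822 CPM, Cd79a, a B cell receptor component, from 0.759 ± 0.0545 to 2.53 ± 0.493 CPM, and Ms4a1, a B cell surface protein gene, from 0.377 ± 0.0443 to 1.83 ± 0.742 CPM. All 24 tested members of the B cell list had positive log2 fold changes with a median of 1.08, of which 3 passed over all genes with edgeR, 12 with DESeq2 and 17 when adjusted over the list alone (camera adjusted p = 1.382e-34; adjusted p = 0.210 with an estimated correlation). The median was 1.252 with the Xist term. Of the most abundant members, Ighm was at 450 ± 25.1 CPM in WT and 453 ± 11.8 CPM in CD103KO, and Cd79b had a log2 fold change of 0.01; neither passed. The erythrocyte and platelet list, 6 tested members with a median of 0.99, also passed upward (camera adjusted p = 4.96e-09; adjusted p = 0.380 with an estimated correlation). EdgeR called 0 of them over all genes (4 at an unadjusted p under 0.05) and 4 adjusted over the list alone, and DESeq2 called 3. Its median was 0.60 with the Xist term, and on the scale of mean log2 CPM relative to the 6 libraries WT replicate 3 (0.0109) lay above CD103KO replicate 3 (-0.0227). Its haemoglobin gene Hba-a2 was at 14.5 ± 2.83 and 29.5 ± 7.20 CPM. Markers of CD4 and regulatory T cells passed upward (median 0.23, camera adjusted p = 0.0293; adjusted p = 0.520 with an estimated correlation). Of 11 members edgeR called 0 (1 at an unadjusted p under 0.05) and 1 adjusted over the list alone, and DESeq2 called 1. In each case the member was Ikzf2, which is also in the T cell receptor signal strength and recent thymic emigrant lists. Of the 11 members, 7 belong to another list too. Cd4 itself was at 0.348 CPM in WT with a negative log2 fold change. This list did not pass without WT replicate 2 (adjusted p = 0.142, median 0.13), without CD103KO replicate 1 (0.0995, median 0.16), without CD103KO replicate 3 (0.1001, median 0.07) or with the Xist term (0.413, median 0.03). Lists for myeloid and dendritic cells (adjusted p = 0.916), NK and innate-like cells (0.678) and lymph node stroma (0.538) did not pass.

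Type I interferon response genes passed upward as a list: 54 of 58 members had positive log2 fold changes, with a median of 0.26, but Xaf1 was the only member called by edgeR, over all genes and adjusted over the list alone (camera adjusted p = 4.148e-25; adjusted p = 0.520 with an estimated correlation). DESeq2 called 4 of the members over all genes. WT replicate 3 lay nearer to the CD103KO mean than to the mean of WT replicates 1 and 2 for 54 of the 58 members, and the list did not pass with the Xist term (adjusted p = 0.0927, median 0.05). Without WT replicate 2 its median was 0.17. Memory and effector CD8 T cell genes passed upward (median 0.07, camera adjusted p = 0.0321; adjusted p = 0.749 with an estimated correlation). Of 42 members edgeR called 0 over all genes or over the list alone (9 at an unadjusted p under 0.05, 7 of them higher), and DESeq2 called Ly6c1. With the Xist term, which sets the CD103KO libraries against WT replicate 3 alone, the median was -0.07. That library had the highest level of the list (0.349 in mean log2 CPM relative to the 6 libraries). The same list did not pass without WT replicate 1 (adjusted p = 0.133, median 0.06), without WT replicate 2 (0.316, median 0.03) or without CD103KO replicate 3 (0.451, median -0.02), and its median was 0.18 without WT replicate 3. Of the genes behind the sort, Ly6c2 was at 22.8 ± 7.25 and 35.8 ± 3.94 CPM in WT and CD103KO (adjusted p = 0.430, edgeR), Ly6c1 at 0.252 ± 0.152 and 0.800 ± 0.248 CPM (0.304, and 0.0363 with DESeq2), and Cxcr3 at 4.71 ± 2.55 and 6.89 ± 1.71 CPM (0.683).

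**Figure D3:**
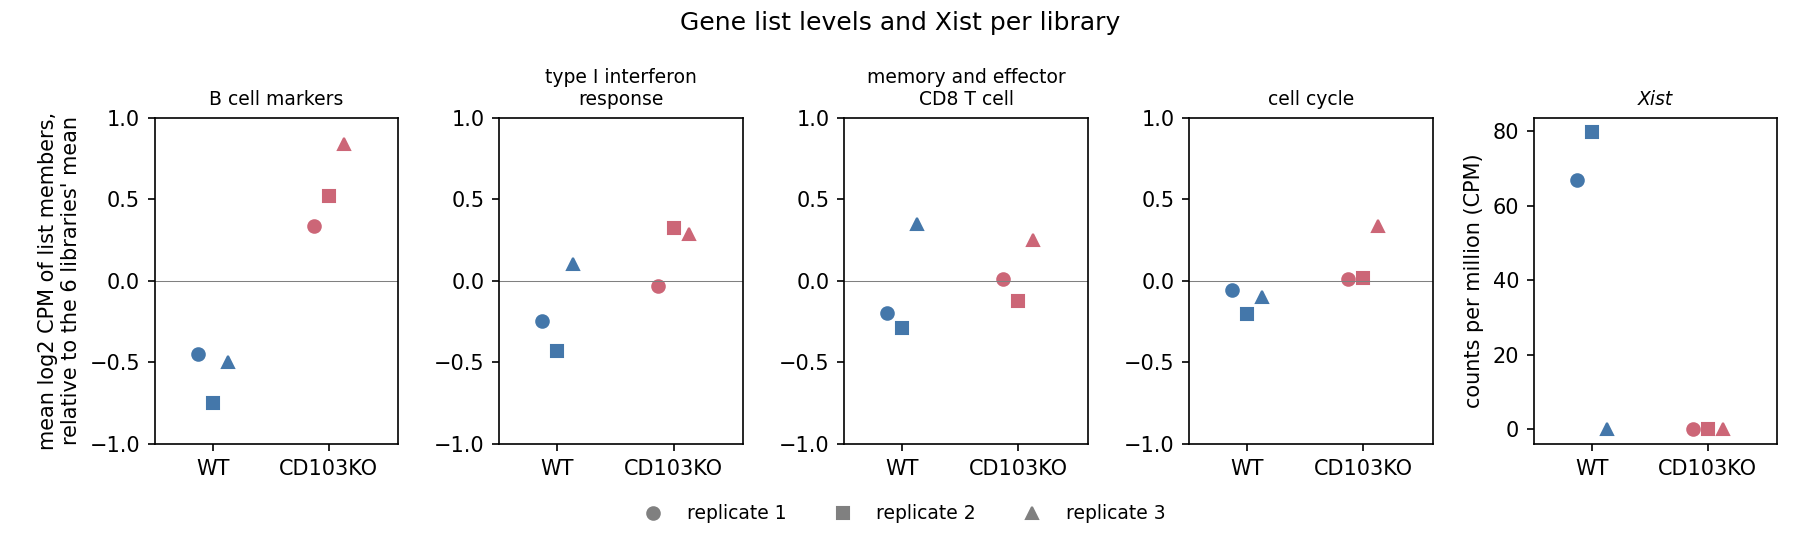
Mean log2 CPM of the members of 4 gene lists relative to the mean of the 6 libraries (first 4 panels), and Xist in CPM (last panel), for each of the 3 WT (blue) and 3 CD103KO (red) libraries. B cell markers lie below the mean in the 3 WT libraries and above it in the 3 CD103KO libraries, while WT replicate 3, which like the CD103KO libraries lacks Xist reads, has the highest level of the memory and effector list (0.349).

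Cell cycle genes passed upward, with 45 of 49 members positive and a median of 0.26 (camera adjusted p = 3.037e-11; adjusted p = 0.704 with an estimated correlation). EdgeR called 0 over all genes (15 at an unadjusted p under 0.05, all higher) and 3 adjusted over the list alone, and DESeq2 called 3, Aurkb and Bub1b among them. The median was 0.12 without CD103KO replicate 3, where the list still passed (adjusted p = 7.269e-05). Aurkb, a mitotic kinase that lies 4.04 Mb from Itgae, was at 1.54 ± 0.0857 and 2.62 ± 0.286 CPM, and Bub1b, a spindle checkpoint kinase, at 4.28 ± 0.173 and 5.96 ± 0.758 CPM. Cytosolic ribosomal protein genes passed downward by a small amount, with 82 of 86 members negative and a median of -0.07 (camera adjusted p = 1.011e-09; adjusted p = 0.749 with an estimated correlation). EdgeR called 0 of them over all genes or over the list alone (16 at an unadjusted p under 0.05, all lower), and DESeq2 called 0. The median was -0.11 with the Xist term. They took 15.9 ± 0.175% of counts in WT and 15.1 ± 0.197% in CD103KO (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). Recent thymic emigrant and immature thymocyte genes passed upward (median 0.07, camera adjusted p = 0.0122; adjusted p = 0.380 with an estimated correlation). Of 20 members edgeR called 0 (4 higher and 1 lower at an unadjusted p under 0.05) and 3 adjusted over the list alone. DESeq2 called 1, again Ikzf2. Cd24a was at 1.97 ± 0.234 and 2.95 ± 0.250 CPM. That list did not pass with the Xist term, although its median of 0.0557 there was close to the 0.0654 without it.

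The lists that define naive CD8 T cells did not pass with all 6 libraries. These were naive and quiescence genes (camera adjusted p = 0.176), where Ccr7, a lymph node homing receptor, was at 486 ± 5.96 and 443 ± 6.37 CPM, and CD8 alpha beta T cell identity genes (0.176), where Cd8a was at 1452 ± 13.4 and 1479 ± 24.9 CPM and Cd8b1 at 1722 ± 55.6 and 1726 ± 31.4 CPM. T cell receptor signal strength genes (0.877), TGF-beta response and tissue residency genes (0.176), integrins and adhesion genes (0.319), chemokine receptor and trafficking genes (0.149) and cytokine receptor genes (0.450) did not pass either, with 0 members called by edgeR in each. At an unadjusted p under 0.05, edgeR gave 3, 8, 3, 5 and 7 members of these 5 lists, and DESeq2 called Tnfaip3 and Ikzf2 of the first and 0 of the others. For naive and quiescence genes edgeR gave 7 of 30, 6 of them lower, and for CD8 identity genes 1 of 25. The count over all tested genes was 1176 of 13470. DESeq2 called 0 naive and quiescence genes, whose median was -0.04, and 0.01 with the Xist term. Tnfaip3, an NF-kappa B inhibitor, had a log2 fold change of -0.33 (adjusted p = 0.0724, edgeR; 6.013e-05 with DESeq2), and Smad7, a TGF-beta target, of -0.20 (0.455). T cell receptor segments (0.916), immediate early genes (0.271), nuclear respiratory chain genes (0.450), mitochondrially encoded genes (0.271), glycolysis genes (0.176, with Eno3 called), MHC class I genes (0.450) and lipid synthesis genes (0.477, with Scd1 called) did not pass. DESeq2 called Nfkbia and Zfp36 of the immediate early list and H2-Q6 of the MHC class I list, all lower, which edgeR did not. Of the lists with 0 members called by edgeR, limma-voom called 0 members too, and with quality weights 1 in each of the T cell receptor signal strength, MHC class I and erythrocyte and platelet lists. Adjusted over the list alone, 1 member was higher and 1 lower among T cell receptor signal strength genes, and 1 was lower in each of the immediate early and MHC class I lists. Without WT replicate 3, CD8 alpha beta T cell identity genes (camera adjusted p = 0.0428, median 0.05) and mitochondrially encoded genes (0.00588, median 0.09) passed upward. In that setting Xist reads separated WT from CD103KO fully. Without WT replicate 2, respiratory chain (0.0478, median -0.03) and MHC class I genes (0.0415, median -0.05) passed downward, as did chemokine receptor genes without CD103KO replicate 3 (0.0497, median -0.07).

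No share of counts passed for a class of transcripts, ribosomal protein genes included, and none could have in this design. Mitochondrially encoded genes held 4.37 ± 0.233% of counts in WT and 4.46 ± 0.249% in CD103KO (exact two-sided permutation p = 0.6), immunoglobulin genes 0.0463 ± 0.00175% and 0.0471 ± 0.00110% (exact p = 0.5), and the 10 most abundant genes 8.74 ± 0.147% and 8.65 ± 0.166% (exact p = 0.5). Haemoglobin genes held 0.00385 ± 0.000862% and 0.00777 ± 0.00186% (exact permutation p = 0.1).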

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

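The fall of Itgae and the excess of calls within 5 Mb of it kept direction and threshold under every alternative run, with Itgae log2 fold changes from -2.91 to -2.81 and odds ratios from 11.2 to 39.3; windows of 1, 10 and 20 Mb gave 26.6, 27.1 and 51.7. None of the 29 called genes besides Itgae reversed under the alternatives run. Of the 66 named genes that did not pass, 14 had the other sign under at least 1 alternative, none of them passing there, and 25 passed under at least 1, 19 of these with DESeq2 and 18 with no filter. RLE and upper-quartile factors and unrounded counts called the same 30 genes.

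The number called, with higher, lower and those beyond 20 Mb of Itgae in that order, rose to 112 (71, 41, 83) with no filter, to 137 (89, 48, 102) with DESeq2 and to 50 (30, 20, 26) with limma-voom and quality weights, each including the 30, and the cause was not tested. It was 19 at an adjusted p of 0.01, with 6 lower and 7 beyond 20 Mb, and 5 genes were lower when tested against a fold of 1.2. With single libraries left out it ranged from 19 to 59 (higher 13 to 33, lower 5 to 26, beyond 20 Mb 7 to 40). It was 52 without WT replicate 3, 59 without CD103KO replicate 1 and 19 without CD103KO replicate 2. The 52 calls compare WT libraries with Xist reads to CD103KO libraries without them. The following settings were chosen after seeing the data, and in each the group effect rests on WT replicate 3 as the only WT library. A term for libraries with Xist reads gave 15 (9, 6, 5), 12 of them among the 30. The libraries without Xist reads alone, where the lone WT sample is assumed to vary like the CD103KO group, gave 13 (9, 4, 5), 10 of them among the 30. The memory and effector list reversed to downward in both (adjusted p = 0.0186 and 0.0111), and was downward with the term and an estimated correlation together (0.767); its adjusted p ranged from 4.132e-05 to 0.767 over all alternatives.

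With an estimated correlation in camera 0 of the 25 lists passed, against 8 with the preset value, and 3 had an unadjusted p under 0.05. With fry 0 passed and 4 had an unadjusted p under 0.05. The Xist term sets the CD103KO libraries against WT replicate 3 alone, so the list results with it rest on that library. With the Xist term 9 lists passed, 5 of them among the 8, of which 4 kept their direction and the memory and effector list turned. The other 4 did not pass without the term and passed downward with it, namely chemokine receptor and trafficking (adjusted p = 0.0132), nuclear respiratory chain (0.00168), mitochondrially encoded (0.0186) and MHC class I genes (0.00303). With the term and an estimated correlation together 0 lists passed, and 2 had an unadjusted p under 0.05. A replicate block gave 24 calls (16 higher, 8 lower), 21 of them among the 30, and 5 calls within 5 Mb of Itgae with an odds ratio of 23.6. Deviations of libraries sharing a number had correlations of -0.199, -0.00535 and -0.0299, and no library correlated best with its own number. These values gave no sign that the numbers pair the samples, but with 3 libraries per group they cannot exclude it. At the filter of 1 CPM in 3 libraries, 25 of the 30 calls were made; how calls depend on depth was not tested.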

Other observations

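The tests of explanations in this part were chosen after the results were seen, apart from the counts over other splits of the libraries. For the latter, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 30 genes and the highest of the others 18, and 1 split in all gave as many as the real one. Within 5 Mb of Itgae the real split called 9 and the highest other 0, again 1 split in all. For gene lists, the real split gave 8 lists and the highest other 14, with 6 splits giving as many as the real one.

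Called genes clustered on chromosome 11 around Itgae, and 6 of the 11 called beyond 20 Mb resembled genes there. A local effect of the targeted allele on neighbours within 1 Mb could cover only 1 of the 18 calls within 20 Mb. The share called within 1 Mb, 5.26% of 19 tested genes, was near the 4.19% of 430 within 20 Mb. For genes that close the counts therefore do not decide. For Haspin, inside Itgae and lower without passing (log2 fold change -1.19, adjusted p = 0.0992, edgeR), such an effect stays open. The lower bound of 22.9 of the odds ratio within 20 Mb argues against loss of CD103 acting wherever genes lie as the cluster's cause. That bound does not test such an effect on the 11 genes that edgeR called beyond 20 Mb, or the 102 that DESeq2 called there. A sex difference between libraries as the cluster's cause is argued against by the odds ratio within 5 Mb, 33.8 with a term for Xist reads. That term rests on WT replicate 3 as the only WT library without Xist reads. A candidate explanation that the tests leave open is a flanking segment of another mouse strain carried with the targeted allele, since calls within 20 Mb had an odds ratio of 51.7, went in both directions and lay on both sides of the gene; genotypes and how reads of another strain align were not analysed here. Reads of near-identical copies inside the segment that were assigned to genes outside it may add to this, since 6 of 11 called genes beyond 20 Mb had such a copy, against 2.203% of 13028 uncalled ones (odds ratio 53.2, 95% interval 13.4 to 222, p = 5.1423e-08, two-sided Fisher's exact test), but reads moved from Cyb5d1 to Gm6685 with nothing else changed are argued against by their sum, which was 1.34 CPM higher in CD103KO where both SDs came to 0.784.

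B cell markers were higher in CD103KO although the cells had been sorted as CD8 T cells. A lower share of CD8 T cells that raises every other cell type alike is argued against by the myeloid and dendritic cell markers. Their 75th percentile of log2 changes was 0.052 against a B cell median of 1.08. Median log2 changes were 0.99 for erythrocytes and platelets and 0.23 for CD4 and regulatory T cells. They were -0.11 for NK and innate-like cells and -0.02 for lymph node stroma. Of 20 tested myeloid and dendritic members, 8 were at 1 CPM or more in WT and 8 belong to another list too. Their median ranged from -0.18 without WT replicate 2 to 0.13 without WT replicate 1. For NK and innate-like cells 2 of 15 tested members were at 1 CPM or more in WT, and for stroma 4 of 6. These values speak against a rise of all other cell types as large as that of the B cell markers. They do not speak against a rise of some, or a smaller one. A sex difference between libraries as the whole cause is argued against by the list's median, 1.252 (quartiles 0.58 to 1.51) with the Xist term, where it passed at the preset correlation (adjusted p = 5.147e-21; with an estimated one it passed neither with the term, 0.572, nor without, 0.210), although the term rests on a single WT library without Xist reads and the 3 called B cell genes lost their calls as standard errors grew (Fcer2a 2.58 to 2.48, Cd79a 1.74 to 1.63 and Ms4a1 2.28 to 2.10 in log2 fold change, standard errors 1.57 to 1.594 times as large). Of the 24 markers 17 were higher in all 3 CD103KO libraries than in all 3 WT libraries, against 918 of 13470 tested genes. This count restates the rise and does not tell its source. B cells among the sorted CD103KO cells may be that source, which the count cannot decide. B cell genes expressed by the CD103KO CD8 T cells themselves cannot be told apart from this in bulk RNA: of the 5 most abundant markers (Ighm, Cd79b, Cd74, Pou2af1 and Ighd) 2 were higher in all CD103KO libraries, Cd74 at 20.04 against 13.3 CPM and Ighd at 10.3 against 6.90 CPM, and the others have a WT level that would hide a small share of B cells (10 of the 24 markers were at 1 CPM or more in WT and 2 belong to another list too).

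Interferon response genes passed upward in CD103KO as a list at the preset correlation, but not with an estimated one (camera adjusted p = 0.520). WT replicate 3, the only WT library without Xist reads, lay nearer to the CD103KO mean for 54 of 58 members, against 52.7% of all tested genes. A sex difference between libraries may therefore account for the list, although it rests on a single WT library and cannot be separated from anything else that sets that library apart. Loss of CD103 or the segment around Itgae stays open as well: with the Xist term the median log2 fold change went from 0.26 (quartiles 0.13 to 0.54) to 0.05 (-0.03 to 0.13), and the call ended because the change shrank (adjusted p = 0.0927, against a range of 7.405e-42 to 0.897 over the alternatives). Of the 24 B cell markers, WT replicate 3 lay nearer to the CD103KO mean for 4.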
